A study of Mus musculus with 20 samples.

How the data were processed

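Lung RNA of 20 female C57BL/6BomTac mice was measured, 5 dams in each of 4 groups. The dams had been given carbon black nanoparticles (Printex 90) into the trachea during pregnancy, or the water vehicle alone, and were killed once their litters had been weaned. Per the labels, RNA was extracted with TRIzol and RNeasy columns, had RNA integrity numbers of 7.0 to 9, and was amplified and labelled by T7 transcription, with the lung sample in Cy5 and a commercial universal mouse reference RNA in Cy3. Each dam had its own two-colour Agilent mouse 4x44K array, and no array had the dyes swapped. The animal number in each title was taken as the replicate, and no number was shared between groups, so no samples were paired.

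The authors deposited, for each array, the spot table of the Feature Extraction software, in which the signals and the local backgrounds of both channels are in scanner intensity units, and the software's own dye ratio, which per the file headers is on the log10 scale. They also deposited a value table that holds the log2 ratio of the lung over the reference channel with no background subtracted, over 43379 features that are not controls, with column medians of -0.05 to -0.0315. The file headers name Feature Extraction 9.5.1.1 for 18 arrays and 10.1.1.1 for 2 arrays, whereas the labels name 9.5.3.1. How the deposited value table was normalised is not given in the sources used here.

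Median spot signals were corrected for local background with the normexp method of limma 3.58.1 (offset 50 intensity units), and the log2 ratio of Cy5 over Cy3, called M here, was normalised within each array by loess with the control spots given no weight. No scaling between arrays was applied. Spots marked as outliers by the software were left out, and the spots of a probe were averaged. A probe was kept when its Cy5 signal lay well above background on at least 3 of the 5 arrays of at least 1 group. The array holds 45018 features, 1639 of them controls, and 41174 different probes, of which 22951 were named through their accession, 6659 through their symbol and 3109 through a synonym in the mouse gene table of GRCm38.p6. The other 8455 probes kept the identifier given in the files. The file headers give the genome builds mm7 or mm8, so the gene table was used for names alone and no coordinates are given. For each gene the probe with the highest mean intensity was used, and a value on at least 16 arrays was required, which left 19914 genes, 15619 of them with a symbol.

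One linear model was fitted per gene over all 20 arrays with limma (lmFit and eBayes), and the contrasts of high, medium and low dose against control, high against medium dose, and a trend over the 4 dose steps were tested two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted. Gene lists with at least 5 measured genes, 33 in all, were tested with limma's camera at a preset correlation between genes of 0.01. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance and, in its mixed form, whether they change in either direction; fry does not compare a list with other genes. Members of a list were also counted with the p-values adjusted over the list alone. Lists share members, such as C3, Cxcl10, Il33, Cd14 and Lcn2, so their tests are not independent. The means of each list per dam were compared by an exact permutation test over the 252 groupings of 5 dams against 5, two-sided, which was chosen after the data had been seen. The model, the lists, the alternative settings and the rule for the genes named were fixed before the data were examined. The steps were tested on simulated data of the same size.

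Genes named for the high dose are the 15 largest rises and the 10 largest falls among genes with a symbol that passed the test and whose dams did not overlap with the controls. For the medium and low dose the rule takes 6 and 4, or the 3 genes with the smallest p where fewer than 3 passed. For each list called by camera, and for the acute phase, chemokine, antioxidant, aryl hydrocarbon receptor and DNA damage lists, the rule takes the 4 members with the smallest p at the high dose. Not all of these are printed for every list. Any other gene was chosen after its values were seen and is introduced as such.

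Slides 1 to 3 each held all 4 groups, slides 4 and 5 held control, low and high dose, and slide 6 held 2 medium-dose arrays only. On the slides with controls, each group had the same position on every slide, so position and group cannot be separated by a model. Differences were recomputed within slides and with the slide as a block. The alternatives were no background correction, the software's log10 ratio, the deposited log2 value table, median centring, scaling between arrays, the Cy5 channel alone, other filters on dim probes, outlier spots kept, the mean of a gene's probes, probes in place of genes, slide or scan date as a block, omission of the slide 6 arrays, the arrays of each contrast alone, eBayes with trend and robust options, array weights, and omission of each array in turn. One alternative was added after the data had been seen: the background model was fitted again without a single spot whose local background lay more than 100 intensity units above its signal. This setting is called the refitted background; the values of the plan fixed in advance stay in front, with the refitted ones beside them. The reference-only Cy3 channel was tested in the same model as a control. Calculations used R 4.3.3 with jsonlite 2.0.0 and the data.table package, version 1.17.8, and Python 3.11.15 with matplotlib 3.10.9 for the figures. The share of probes above background describes the depth of each array, and the number of arrays limits the precision of every value.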

Results

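Gene expression was measured in the lungs of 20 mouse dams that had received carbon black, an industrial soot-like nanoparticle, by instillation into the trachea 4 times during pregnancy, between gestational days 7 and 18. The groups were 5 dams given water alone and 5 dams each given a total of 11 µg (low), 54 µg (medium) or 268 µg (high dose). Lungs were taken 26 to 27 days after exposure, when the pups had been weaned. Each lung sample was hybridised in Cy5 to its own array against a common reference RNA in Cy3, so every value is a log2 ratio of lung over reference, called M. The Cy5 signal was well above background for 71.5% ± 3.8 (SD, n = 5) of the probes in controls, 72.4% ± 2.35 at the low dose, 69.1% ± 4.77 at the medium dose and 72.8% ± 3.45 at the high dose. The median Cy5 signal of an array lay between 161.5 and 246.5 intensity units, over a median local background of 80 to 83. Correlations of M between any 2 arrays ranged from 0.918 to 0.988 across genes, which are not independent replicates. The array of low-dose dam 27 stood apart: its M values had a slope of 0.704 on the mean of the other arrays, against 0.964 to 1.06 for the others. With the background model of that array refitted without 1 spot, a choice made after the data had been seen, the slope was 0.999 and those of the others were 0.949 to 1.04. The low-dose values and the spread shared by all comparisons therefore carry this array's compressed ratios, and counts with the refitted background are given beside them. The number of arrays limits the precision. In simulated data of the size of the high-dose comparison (19914 genes), the same test recovered 79% of 100 genes changed by 0.5 and 95% of 100 genes changed by 1 on the log2 scale. Of its 184 calls 10 were false. The simulated noise was independent between genes and arrays, with no slide effect, and many planted changes ease the adjusted threshold. These shares are therefore not the power in the real data.

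**Figure D1:**
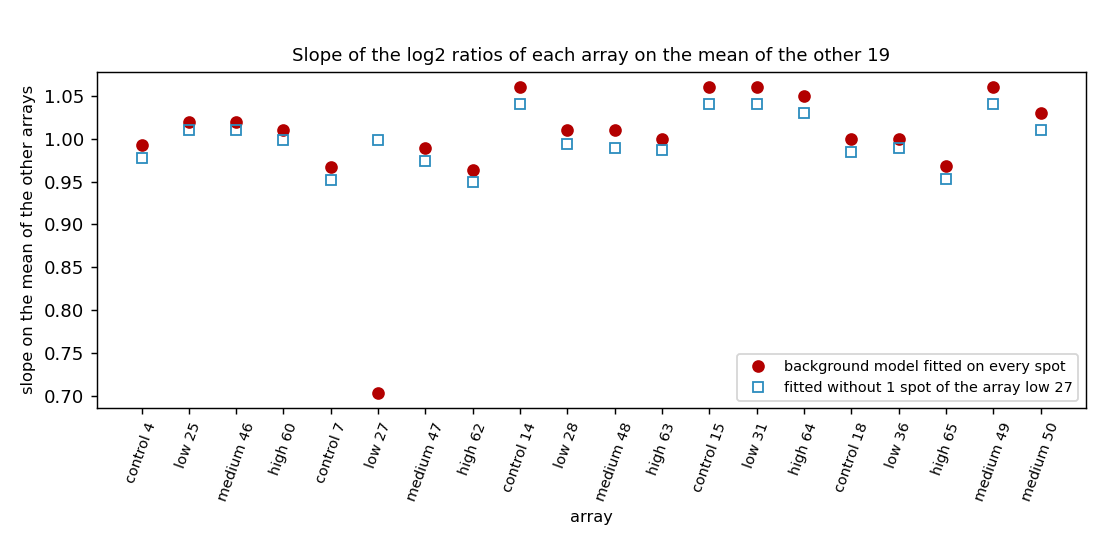
Slope of each array's M values on the mean M of the other 19 arrays, with the background model fitted to all spots and with 1 spot left out. The array of low-dose dam 27 has a slope of 0.704 with all spots and 0.999 without the spot, and the other arrays lie between 0.949 and 1.06 in both settings.

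The comparison of the high dose with the water control asked which lung genes differ 26 to 27 days after exposure. Cxcl5, a chemokine that attracts neutrophils, rose the most of the named genes, 8.25-fold (log2 3.04 ± 0.42, SE, n = 5 per group, adjusted p = 0.00357). Trem2, a lipid-sensing receptor of macrophages, rose 1.98-fold (log2 0.99 ± 0.14), and Ly6f, a member of the Ly6 family of surface proteins, rose 3.25-fold (log2 1.70 ± 0.23), both at an adjusted p of 0.00357. Noxo1, the organiser subunit of NADPH oxidase 1, rose 2.21-fold (adjusted p = 0.021). Clec5a, a C-type lectin receptor of myeloid cells, rose 1.71-fold (adjusted p = 0.0282), and C3ar1, the receptor for complement fragment C3a, rose 1.38-fold (adjusted p = 0.021). Ccl20, a chemokine for dendritic cells and lymphocytes, and Lemd1, a LEM domain protein, had a Cy5 signal well above background on 0 of 5 control arrays and on 4 of 5 high-dose arrays. In M, Ccl20 rose by 0.44 ± 0.08 (adjusted p = 0.0282) and Lemd1 by 0.69 ± 0.12 (adjusted p = 0.021) on the log2 scale. In the Cy5 signal alone, a separate quantity that was not the one tested, the dim controls leave lower bounds of at least 1.29-fold for Ccl20 and at least 1.82-fold for Lemd1. The olfactory receptor gene Olfr32 rose 1.19-fold (adjusted p = 0.0338), but its Cy5 signal alone, without the reference, changed by -0.04 on the log2 scale. For each of these 9 genes every high-dose dam lay above every control, and so on 5 of 5 slides, because the naming rule required it. Within slides the difference was 1.74 to 4.38 for Cxcl5, 0.715 to 2.29 for Ly6f, 0.605 to 1.38 for Trem2 and 0.231 to 1.62 for Noxo1. It was 0.477 to 1.15 for Clec5a, 0.182 to 0.906 for Lemd1, 0.312 to 0.565 for C3ar1, 0.164 to 0.66 for Ccl20 and 0.14 to 0.353 for Olfr32. For Clec5a the kept probes differed, with log2 changes of 0.167 and 0.777.

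In all, 14 of 19914 genes rose and 0 fell at the high dose by limma, 10 of the 14 with a symbol and 9 by more than 1.5-fold. At an unadjusted p under 0.05 there were 1123 higher and 872 lower genes, where 996 in all would be expected by chance. The dams of the groups did not overlap for 504 genes (2.53%, against 0.794% by chance). That chance share is an average over groupings. Genes that vary together can move the share in a single grouping, so the excess is not a test. The calls outside the naming rule, listed after their values were seen, were Ms4a7, a membrane protein of macrophages (log2 0.96 ± 0.17, adjusted p = 0.0338, with overlapping dams), and 4 transcripts without a symbol, M19902, LOC668423, AK048646 and AK053298. After the background was refitted, 61 genes passed, 37 higher and 24 lower, among them all 14. Genes that passed there but not with the background model of the plan included Siglech, a receptor of plasmacytoid dendritic cells (log2 -0.31, adjusted p = 0.0230), Siglecf, a receptor of alveolar macrophages and eosinophils (-0.80, adjusted p = 0.0339), and Ear6, an eosinophil-associated ribonuclease (-0.59, adjusted p = 0.0194), whose dams all lay below the controls. These 3 also passed without background correction, with the deposited value table and without low-dose dam 27, and their adjusted p over all alternatives ranged from 0.0014 to 1, 0.00392 to 0.847 and 0.00319 to 0.789. Also among the genes passing with the refitted background, chosen after their values were seen, were Klra8 (-0.76, adjusted p = 0.0304) and Klrb1a (-0.57, adjusted p = 0.0194), receptors of natural killer cells. With the slide as a block 13 genes passed, and the adjusted p was 0.0164 for Cxcl5 and Trem2, 0.0206 for Ly6f. Noxo1 (adjusted p = 0.0663) and Olfr32 (adjusted p = 0.0668) were then not called. Over all alternatives the adjusted p ranged from 0.000402 to 0.128 for Cxcl5, 1.09e-06 to 0.162 for Ly6f, 0.000238 to 0.193 for Trem2, 0.000402 to 0.162 for Noxo1 and 0.00332 to 1 for Olfr32. Tested on the 10 arrays of these groups alone, 1 gene passed, and it was lower, not among the 14. The count was 59 without low-dose dam 27 and 41 without high-dose dam 60. It was 4 without control 7 or high-dose dam 62, 5 without control 15, control 18 or high-dose dam 63, and 9 without high-dose dam 65. Cxcl5, Ly6f and Trem2 passed in each of these 20 omissions, with adjusted p up to 0.0202. Omission of control 7, 15 or 18 or high-dose dam 62 or 63 ended each other named call, as did high-dose dam 65 except for Ccl20. So did control 4 for Clec5a and Olfr32, and control 14 or high-dose dam 64 for Ccl20 and Olfr32. The adjusted p then reached 0.0948 for Noxo1, Lemd1 and C3ar1, 0.118 for Clec5a and Ccl20, and 0.143 for Olfr32. The Olfr32 call also ended without low-dose dam 25, 28 or 36 or medium-dose dam 47, 49 or 50.

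**Figure D2:**
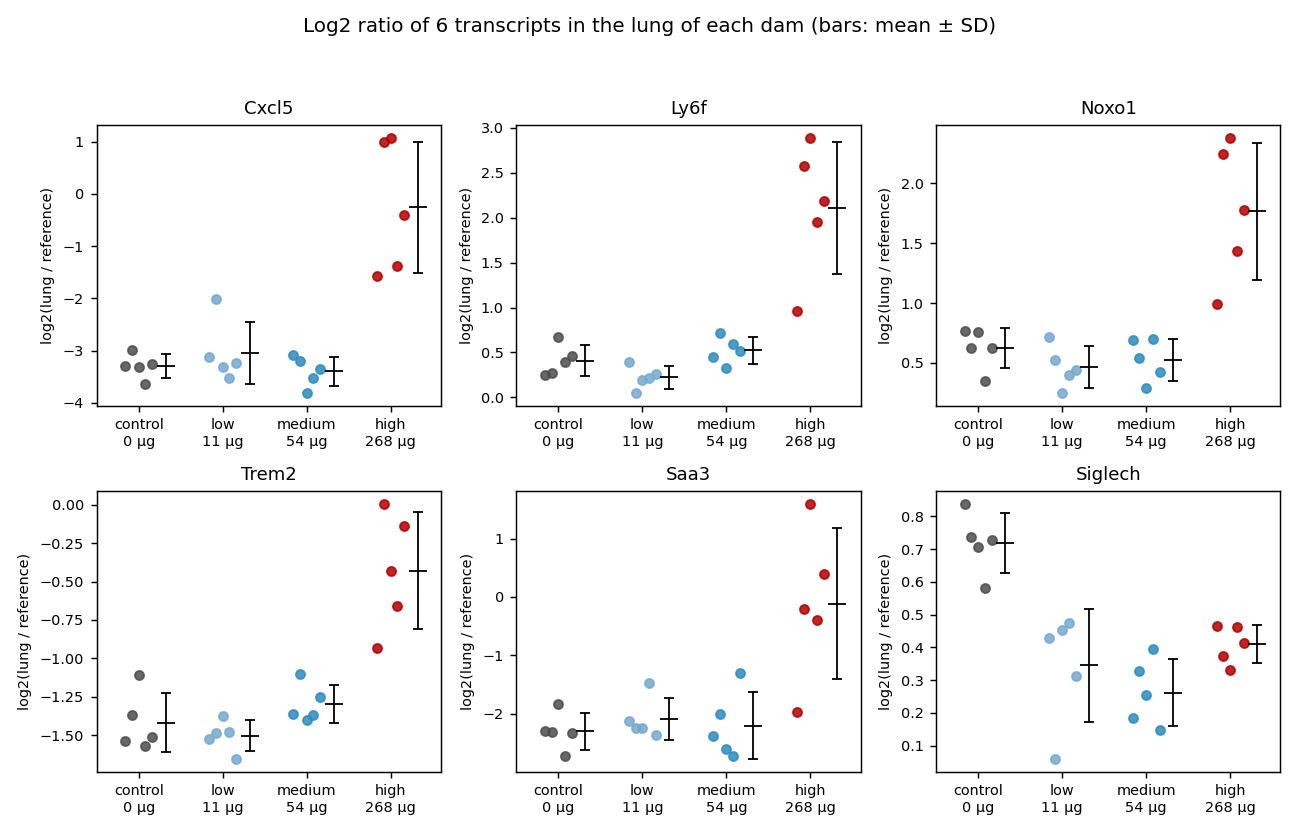
M (log2 of lung over reference) of Cxcl5, Ly6f, Noxo1, Trem2, Saa3 and Siglech in each of the 20 dams by dose group, with the group mean and SD (n = 5). Cxcl5 averages -3.30 in controls and -0.25 at the high dose, while the low and medium groups differ from the controls by 0.26 and -0.10.

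Genes of inflammation had positive median changes as groups at the high dose, although most single members did not pass over all genes. Camera called lists as readily in other splits of the arrays: 57 of 100 splits, the real one included, gave at least the real 12. A camera call alone therefore does not exclude chance. Of 31 measured chemokines, the secreted proteins that draw in leukocytes, 2 rose over all genes and 12 rose and 1 fell when adjusted over the list alone. Their median log2 change was 0.36 (camera adjusted p = 2.21e-10, but adjusted p = 0.167 with an estimated correlation). Besides Cxcl5 and Ccl20 they included Ccl7, a monocyte chemokine (1.30 ± 0.27, adjusted p = 0.0793 over all genes and 0.00107 over the list alone), and Cxcl3, a neutrophil chemokine (0.55 ± 0.12, adjusted p = 0.104 over all genes). Of 23 acute phase proteins, which are made in quantity during inflammation, 0 rose over all genes by limma and 6 rose adjusted over the list alone. Their median was 0.37, with a camera adjusted p of 2.01e-07, but adjusted p = 0.248 with an estimated correlation. Serum amyloid A genes led that list, with log2 changes of 2.19 ± 0.44 for Saa3 (adjusted p = 0.0691 over all genes) and 1.15 ± 0.25 for Saa1 (adjusted p = 0.0955). The iron-binding protein Lcn2 differed by 1.13 ± 0.25 and the complement protein C3 by 0.74 ± 0.16, and each of these 4 had an adjusted p of 0.00126 over the list alone. Of 40 genes of particle-laden or lipid-associated macrophages, 1 (Trem2) rose over all genes and 11 rose adjusted over the list alone. Among the 11 were the elastase Mmp12 (0.92 ± 0.21), the scavenger receptor Msr1 (0.80 ± 0.21) and the lysosomal protease Ctsd (0.48 ± 0.14). That list had a median of 0.19, a camera adjusted p of 2.01e-07 and an adjusted p of 0.482 with an estimated correlation. The dams overlapped with the controls for Cxcl3, Saa3, Lcn2, C3, Msr1 and Ctsd, and did not for Ccl7, Saa1 and Mmp12. High-dose dam 60 lay below the highest control for Saa3 (M of -1.97 against -1.84) and Lcn2 (1.83 against 2.01).

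Complement genes were higher too: of 22 measured, 1 (C3ar1) rose over all genes and 3 adjusted over the list alone. Their median was 0.22 (camera adjusted p = 7.83e-06, adjusted p = 0.487 with an estimated correlation). The protease gene C1ra, at 0.38 ± 0.08, was among the 3. Of 35 interferon-stimulated genes, 0 rose over all genes by limma and 1 adjusted over the list alone, Cxcl10 (0.87 ± 0.22). That list had a median of 0.18, a camera adjusted p of 3.03e-07 and an adjusted p of 0.79 with an estimated correlation. Of 29 inflammatory cytokine genes, 4 rose adjusted over the list alone and 0 over all genes by limma. They were the interleukin 1 antagonist Il1rn (0.53 ± 0.12), the growth factor Csf2 (0.68 ± 0.17), the alarmin Il33 (0.56 ± 0.16) and the signalling inhibitor Socs3 (0.30 ± 0.09). The cytokine list had a median of 0.11 and a camera adjusted p of 0.015, which became an adjusted p of 0.487 with an estimated correlation. B cell and plasma cell genes had a median of 0.12 over 30 members (camera adjusted p = 0.00208, adjusted p = 0.909 with an estimated correlation). The antibody joining chain Jchain differed by 1.78 ± 0.36, the plasma cell receptor Tnfrsf17 by 0.80 ± 0.18 and the antibody heavy chain Ighg1 by 0.89 ± 0.26. These 3 rose adjusted over the list alone and 0 rose over all genes by limma. In contrast, 19 neutrophil markers had a median of -0.21 (camera adjusted p = 0.015, adjusted p = 0.92 with an estimated correlation). The granule protein genes Camp (-1.20 ± 0.34) and Ngp (-0.95 ± 0.29) fell adjusted over the list alone, with every high-dose dam below every control. For C1ra, Cxcl10, the 4 cytokine genes and the 3 antibody and plasma cell genes, the dams overlapped with the controls.

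The mean over a list's members was higher in the high-dose dam than in the control on 5 of 5 slides for chemokines (by 0.218 to 0.704), acute phase proteins (0.214 to 0.873) and macrophage genes of particle uptake (0.013 to 0.566). The same held for complement (0.0123 to 0.475), interferon-stimulated genes (0.0172 to 0.643) and cytokines (0.0617 to 0.204). It was higher on 3 of 5 for B and plasma cell genes and on 1 of 5 for neutrophil markers. In all, 12 of 33 lists passed at the high dose, 9 higher and 3 lower, and 11 of these, and no other, after the refit. With an estimated correlation 0 passed, against 1 by fry (chemokines, adjusted p = 0.032) and 5 by its mixed form (chemokines, acute phase proteins, cytokines, complement and the particle-laden macrophage list). In an exact permutation test of the mean per dam, chemokines and acute phase proteins differed by 0.484 and 0.464 and reached the smallest p that the 252 groupings allow, 0.00794 two-sided. After adjustment over the 33 lists 0 passed (lowest adjusted p 0.131). The cytokine call ended without high-dose dam 62 (adjusted p = 0.0836) or 63 (0.0998). The B and plasma cell call ended without high-dose dam 62 (0.0609) or 65 (0.218), and the neutrophil call without control 14 (0.42) or high-dose dam 65 (0.131). Without high-dose dam 62, 6 lists passed.

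**Figure D3:**
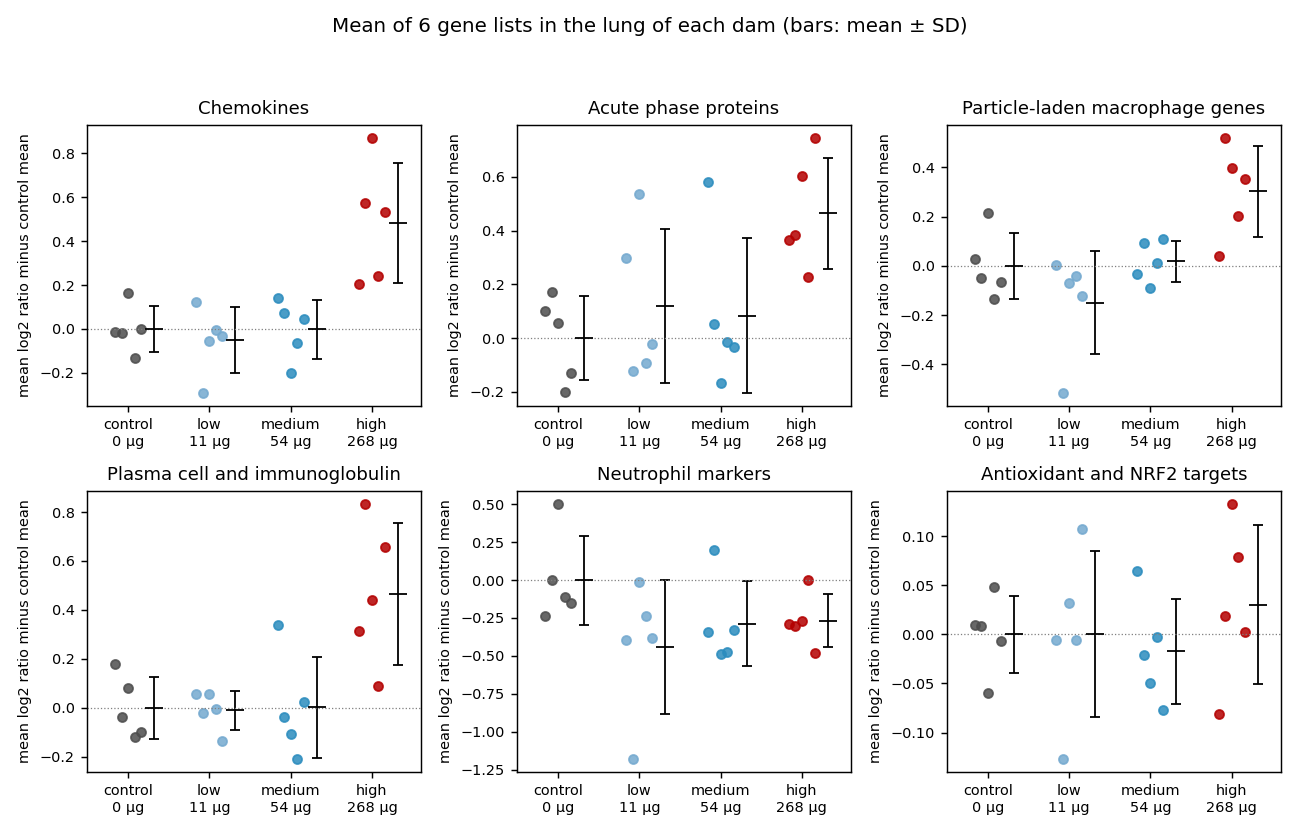
Mean M of the members of 6 gene lists in each of the 20 dams, minus the control mean (log2), by dose group with the group mean and SD (n = 5). The high-dose group mean is 0.484 for chemokines and 0.464 for acute phase proteins, and -0.267 for neutrophil markers.

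Lists of other lung functions and cell types were called at the high dose as well. Cholesterol synthesis and sterol-regulated genes had a median of 0.11 over 26 members (camera adjusted p = 0.00708, adjusted p = 0.909 with an estimated correlation). Ch25h, which makes an oxidised sterol, stood at 0.89 ± 0.25 and the synthesis enzyme Hmgcs1 at 0.33 ± 0.12. Surfactant and alveolar type 2 genes had a median of 0.10 over 21 members (camera adjusted p = 0.015, adjusted p = 0.92 with an estimated correlation). Smooth muscle and fibroblast genes had a median of -0.08 over 24 (adjusted p = 0.0304, or an adjusted p of 0.909 with an estimated correlation) and proliferation genes -0.07 over 38 (adjusted p = 0.0374, or an adjusted p of 0.92 with an estimated correlation). Adjusted over the list alone, Il33 rose in the surfactant list, the contractile protein gene Smtn fell in the smooth muscle list (-0.25 ± 0.06), and 0 genes passed in the sterol and proliferation lists. Over all genes 0 passed in each of these 4 lists by limma. The proliferation call did not hold with the refitted background (adjusted p = 0.0618). It also ended without control 7 (0.27), control 14 (0.625), control 18 (0.065), low-dose dam 27 (0.072) or high-dose dam 62 (0.537), 64 (0.7) or 65 (0.0518). The surfactant call ended without control 7 (0.139) or 18 (0.121) or high-dose dam 62 (0.0836) or 63 (0.0838), and the sterol call without control 14 (0.081) or high-dose dam 62 (0.159) or 63 (0.0595). The smooth muscle call ended without control 14 (0.081) or 15 (0.0741) or high-dose dam 62 (0.0836), 64 (0.0531) or 65 (0.0594).

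The lists tied to known modes of action of soot particles did not pass at the high dose. Antioxidant and NRF2 target genes had a median of 0.00255 over 37 members (camera adjusted p = 0.498). The cystine transporter Slc7a11 stood at 0.49 ± 0.14 (adjusted p = 0.25, or 0.0358 with the refitted background). Aryl hydrocarbon receptor and xenobiotic genes had a median of 0.013 over 25 members (adjusted p = 0.777), with the cytochromes Cyp1a1 at -0.45 ± 0.24 and Cyp1b1 at 0.52 ± 0.22. DNA damage and p53 target genes had a median of 0.02 over 34 members (adjusted p = 0.498), with Gadd45g at 0.33 ± 0.11. In these 3 lists 0 members passed adjusted over the list alone by limma. Collagen and matrix genes had a median of -0.00942 and a mean of 0.0363 over 44 members, with the test pointing up (adjusted p = 0.777).

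Among cell types, macrophage identity genes had a median of 0.03 over 19 members (adjusted p = 0.132), where the members that passed adjusted over the list alone included Aif1 and Cd14, which rose, and Siglecf, which fell. T and natural killer cell genes had a median of -0.03 over 28 members (adjusted p = 0.451), with the killer cell perforin Prf1 at -0.61 ± 0.22 and the receptor Klrb1c at -0.60 ± 0.24. Eosinophil and mast cell genes had a median of -0.014 (adjusted p = 0.502), and dendritic cell and MHC class II genes 0.06 (adjusted p = 0.498), where Siglech fell adjusted over the list alone. Alveolar type 1 genes had a median of -0.01 (adjusted p = 0.63), airway secretory genes 0.03 (adjusted p = 0.502), and ciliated cell genes 0.04 (adjusted p = 0.544). Endothelial genes had a median of 0.03 (adjusted p = 0.673), mitochondrial respiration genes 0.03 (adjusted p = 0.544) and red cell and platelet genes -0.07 (adjusted p = 0.498). Markers of tissue that dissection could bring along gave medians of -0.01 for heart and skeletal muscle (mean 0.03, adjusted p = 0.776), and 0.09 for fat (adjusted p = 0.498). They gave 0.05 for thymus and lymph node (adjusted p = 0.544) and 0.03 for cartilage, thyroid and squamous epithelium (adjusted p = 0.498). Immediate early genes gave 0.03 (adjusted p = 0.451) and glucocorticoid-induced genes -0.07 with a mean of 0.01 and a test pointing up (adjusted p = 0.776). Clock genes gave -0.25 (adjusted p = 0.224, and 0.0433 with the slide as a block, where they were called lower).

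The comparison of the medium dose with control asked whether 54 µg in place of 268 µg left a trace. By limma 0 of 19914 genes passed, with 1827 genes at an unadjusted p under 0.05, 1055 higher and 772 lower. The smallest p belonged to Siglech, a receptor of plasmacytoid dendritic cells, at -0.46 ± 0.07 (adjusted p = 0.0993), with all 5 medium-dose dams below all controls and values of -0.654 to -0.408 on 3 of 3 slides. Next by p were Tlnrd1, which encodes a talin rod domain protein (0.54 ± 0.09, adjusted p = 0.152), and the matrix protein gene Adamtsl3 (-0.34 ± 0.07, adjusted p = 0.317). Of the genes that rose at the high dose, Cxcl5 stood at -0.10, Ly6f at 0.11, Trem2 at 0.12 and Noxo1 at -0.10, while Olfr32 stood at 0.17, against 0.25 at the high dose. With the refitted background 1 gene passed, Siglech, which was lower (-0.46, adjusted p = 0.00222), and with the slide as a block it did not pass (-0.46, adjusted p = 0.687), with a range of 7.78e-05 to 1 over all alternatives. The count was also 1 without low-dose dam 27 or medium-dose dam 46, and dams did not overlap for 550 genes (2.76%, against 0.794% by chance). This share is again not a test, and it was no smaller than at the high dose, where genes passed.

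At the medium dose 8 of 33 lists passed with camera, 3 higher and 5 lower, and after the refit 15 passed, among them all 8. Of 100 splits of the arrays, the real one included, 79 gave at least 8 lists, so these calls do not exclude chance. Of the 33, 0 passed with an estimated correlation or by fry, and within the 8 called lists 0 members passed adjusted over the list alone. Heart and skeletal muscle genes, markers of tissue that dissection could bring along, had the largest median, -0.60 over 32 members (adjusted p = 2.1e-05). Collagen and matrix genes had a median of -0.15 (adjusted p = 2.1e-05), proliferation genes -0.18 (adjusted p = 2.18e-07), smooth muscle and fibroblast genes -0.14 (adjusted p = 0.000306) and neutrophil markers -0.33 (adjusted p = 0.00811). Interferon-stimulated genes had a median of 0.12 (adjusted p = 0.00811), surfactant and alveolar type 2 genes 0.12 (adjusted p = 0.0101) and cartilage, thyroid and squamous genes 0.08 (adjusted p = 0.0365). Each of the 8 had an adjusted p of 0.909 with an estimated correlation. With the slide as a block the neutrophil (adjusted p = 0.152), surfactant (0.761) and cartilage (0.122) lists were not called. The heart and muscle list kept its call (0.0428) although its mean was higher than control on 2 of 3 slides, from -1.1 to 0.133. Chemokines (median -0.01 with a test pointing up, adjusted p = 0.777) and acute phase proteins (0.06, adjusted p = 0.649) did not pass. The neutrophil call ended without control 14 (0.262) or medium-dose dam 49 (0.0646), and the interferon call without control 4 (0.134) or medium-dose dam 47 (0.0654). The surfactant call ended without control 7 (0.0884), control 18 (0.0852) or medium-dose dam 49 (0.0846) or 50 (0.0553). The cartilage call ended without medium-dose dam 46 (0.17) or 47 (0.0587) or control 14 (0.107), 15 (0.0821) or 18 (0.0964). Without medium-dose dam 46, 13 lists passed.

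The comparison of the low dose with control asked the same of the smallest dose, and its values carry the compressed array of low-dose dam 27. By limma 0 of 19914 genes passed, with 1471 genes at an unadjusted p under 0.05, 533 higher and 938 lower. With the refitted background 0 passed as well (1329 at an unadjusted p under 0.05). Siglech, the plasmacytoid dendritic cell receptor, differed by -0.37 ± 0.07 (adjusted p = 0.656), with all 5 low-dose dams below all controls and values of -0.678 to -0.108 within slides. Pld4, an endolysosomal nuclease of dendritic cells, stood at -0.48 ± 0.10 and the dioxygenase gene Ado at 0.22 ± 0.05, each at an adjusted p of 0.656 and with dams that did not overlap. Dams did not overlap for 275 genes (1.38%, against 0.794% by chance on average over groupings, again not a test).

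At the low dose 9 of 33 lists passed with camera, 2 higher and 7 lower. Of 100 splits of the arrays, the real one included, 73 gave at least 9 lists, so these calls do not exclude chance. Only after the refit were complement (adjusted p = 0.0138), surfactant and alveolar type 2 (0.00441), alveolar type 1 (0.00304) and endothelial genes (0.0401) called, all higher. The refit called 9 lists in all, and 5 of the first 9 were among them, in the same direction. Among these 5 were macrophage identity genes (median -0.27, adjusted p = 2.08e-05 and, refitted, -0.16, adjusted p = 6.53e-05) and neutrophil markers (-0.54, adjusted p = 2.68e-05 and, refitted, -0.39, adjusted p = 3.25e-05). So were T and natural killer cell genes (-0.26, adjusted p = 0.00261 and, refitted, -0.11, adjusted p = 0.00364), proliferation genes (-0.13, adjusted p = 0.0152 and, refitted, -0.15, adjusted p = 7.97e-06) and immediate early genes (0.10, adjusted p = 0.00261 and, refitted, 0.08, adjusted p = 0.00304). Ciliated cell genes (-0.23, adjusted p = 0.00261), eosinophil and mast cell genes (-0.18, adjusted p = 0.0152), particle-laden macrophage genes (-0.08, adjusted p = 0.0251) and cartilage, thyroid and squamous genes (0.09, adjusted p = 0.0251) were called only in the first setting. With the refitted background their adjusted p was 0.948, 0.0569, 0.0541 and 0.461. Each of the 9 had an adjusted p of 0.872 with an estimated correlation, and 0 lists passed with it or by fry. Adjusted over the list alone, 4 of 19 macrophage identity genes fell and 0 passed in the other 8 lists by limma. Within slides the list mean was lower than control on 5 of 5 slides for neutrophil markers (by -1.18 to -0.124) and on 4 of 5 for macrophage identity genes. Without low-dose dam 27 the ciliated (adjusted p = 0.153), eosinophil (0.127), particle-laden macrophage (0.155) and cartilage (0.793) lists were not called. The proliferation call ended without control 7 (0.133) or 14 (0.35) or low-dose dam 25 (0.279) or 31 (0.342), and the eosinophil call without control 14 (0.102) or low-dose dam 36 (0.0574). The particle-laden macrophage call ended without control 14 (0.253) or low-dose dam 36 (0.0566), and the cartilage call without control 14 (0.0697), 15 (0.0684) or 18 (0.112).

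High and medium dose were compared directly, since a gene that passes at one dose and not at the other need not differ between them. Cxcl5 was 8.84-fold higher at the high than at the medium dose (log2 3.14 ± 0.42, adjusted p = 0.00904), Ly6f higher by 1.59 ± 0.23 (adjusted p = 0.013), Noxo1 by 1.24 ± 0.19 and Trem2 by 0.87 ± 0.14 (both adjusted p = 0.0134). By limma 6 genes were higher and 0 lower, the other 2 being the transcripts LOC628098 and M19902, which have no symbol, and 1499 genes had an unadjusted p under 0.05. Clec5a (0.74 ± 0.14, adjusted p = 0.0603), Lemd1 (0.54 ± 0.12, adjusted p = 0.127), C3ar1 (0.34 ± 0.08, adjusted p = 0.173), Ccl20 (0.31 ± 0.08, adjusted p = 0.228) and Olfr32 (0.08 ± 0.05, adjusted p = 0.743) did not pass. Chemokines had a median difference of 0.31 (camera adjusted p = 3.47e-10), acute phase proteins 0.21 (5.46e-07) and particle-laden macrophage genes 0.15 (6.35e-08), but with an estimated correlation the adjusted p was 0.178, 0.2 and 0.302. Over the list alone 13, 6 and 10 members were higher, and over all genes 1, 0 and 1. Markers of heart and skeletal muscle differed as well, by a median of 0.58 (5.46e-07, adjusted p = 0.498 with an estimated correlation). With the refitted background 19 genes passed, all higher and including the 6. With the slide as a block 1 gene passed, and without the 2 medium-dose arrays of the slide that held no other group 0 passed. The count was 0 without medium-dose dam 48, 1 without medium-dose dam 50, 3 without medium-dose dam 49, 12 without control 4, 19 without high-dose dam 64 and 34 without high-dose dam 60.

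The trend over the 4 dose steps was a linear contrast, which a gene that changes only at the high dose can also pass. The fitted slope per step was 0.88 for Cxcl5 (adjusted p = 0.0108), 0.54 for Ly6f and 0.32 for Trem2 (both adjusted p = 0.00366). By limma 15 genes rose and 0 fell, with 2059 at an unadjusted p under 0.05, and 11 of the 15 have a symbol. These are the 10 called at the high dose and Tgoln1, a protein of the trans-Golgi network, chosen after its values were seen. At the low and medium doses Cxcl5, Ly6f and Trem2 differed from control by -0.19 to 0.26 on the log2 scale. The 0.26 is Cxcl5 at the low dose, which was -0.004 with the refitted background. The slopes of these genes therefore come from the high dose and not from a steady rise. After the refit 56 genes passed, 35 higher and 21 lower, 14 of them among the 15. The count was 63 without low-dose dam 27, 36 without high-dose dam 60, 4 without control 7, 5 without control 18 or high-dose dam 62 or 63, 6 without control 15 and 9 without high-dose dam 65.

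Whether the lower doses moved the same genes the same way was asked of the 14 genes called at the high dose. Of these, 11 (78.6%) had the same sign at the medium dose and 7 (50%) at the low dose, among them C3ar1 (0.12 and 0.15) and Olfr32 (0.17 and 0.14) at both. All doses share the same 5 controls, and with unchanged groups simulated against shared controls 90.1% had the same sign on average, from 7.14% to 100%. The simulation held no change at any dose, whereas the 14 real genes include large rises at the high dose. Its share is therefore not the one chance would give for them, and its wide range can exclude little. With the controls split so that the doses did not share them, 60.7% had the same sign at either dose. With the refitted background 55 of 61 genes (90.2%) had the same sign at the medium and 47 of 61 (77%) at the low dose. There the unchanged groups simulated gave 90.1% on average, with the same limit, and split controls gave 64.1% at the medium and 57% at the low dose. With the planned background the share at the low dose was 79.7% without low-dose dam 27.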

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

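The tests of the compressed array, of immune cells and of lymph node tissue below were chosen, or redefined, after the result had been seen. Within each dose group of 5 dams, a dam was singled out where its gap to the nearest other dam took up most of the group's range. This held in 46 of 492 groups of values (9.35%), where chance picks out about 1 in 20: 3 of 16 for array measures, 29 of 396 for named genes and 14 of 80 for gene lists. Low-dose dam 27, with its compressed ratios, made up 2 of the 3, 11 of the 29 and 6 of the 14. Without these the share lies near that of chance, so the other dams listed below need not be unusual.

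The array of low-dose dam 27 lay apart from the other low-dose arrays on the first principal component (-56.03, others -2.579 to 12.27) and in its spread around the group mean (SD 0.3517, others 0.1487 to 0.1954), and its M values were compressed toward 0. A background model distorted by 1 spot is a candidate cause: that spot had a local Cy3 background of 34578.5 over a signal of 48. With the spot, the fitted Cy3 background had a mean of -323 and an SD of 338, against 10.8 and 1.64 without it. The other arrays had means of 6.09 to 17.9 and SDs of 0.336 to 2.02. Without the spot the slope of M was 0.999 and the spread around the group mean 0.157, so the compression did not remain. Lung RNA of another makeup, or mixed with the reference, is argued against by the scanner's own log ratio, whose slope for this array was 0.944, within the 0.888 to 1.06 of the other arrays. Other biological explanations for this dam were not tested.

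With the planned background, in which this array was compressed, the values of dam 27 that stood apart lie mostly nearer to 0 than those of the other low-dose dams. For chemokine, growth factor and plasma cell genes they were Ccl7 -2.56 (others -3.319 to -3.128), Cxcl5 -2.01 (-3.523 to -3.118), Csf2 0.4134 (1.231 to 1.365) and Derl3 -0.9581 (-1.909 to -1.642). For eosinophil, natural killer and ciliated cell genes they were Ear1 2.741 (4.109 to 4.637), Siglecf 0.7042 (1.914 to 2.331), Klrb1c 0.7308 (2.055 to 2.429), Dnaic1 0.7035 (1.212 to 1.397), Drc1 3.069 (3.843 to 4.071) and Tctex1d4 0.2883 (0.7416 to 0.8752). The transporter gene Slc7a11 stood at -0.2175 (-1.144 to -0.9021). As means over lists, relative to controls, the dam had -0.777 for ciliated cell, -0.8 for eosinophil and mast cell, -0.516 for particle-laden macrophage, -0.82 for macrophage identity, -0.823 for T and natural killer cell and 0.429 for cartilage, thyroid and squamous genes.

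The genes higher at the high dose include Cxcl5, Ly6f and Trem2. An effect of position on the slide cannot be told apart from the dose, because each group held the same position on every slide with controls. The Cy3 reference, whose median change over the called genes was -0.0124 of that in M, does not decide it, since an effect equal in both dyes cancels in M and single genes changed both ways in Cy3 (Ly6f 0.28, Olfr32 -0.19). Whether immune cells of every kind were more numerous was asked of the T and natural killer, neutrophil and eosinophil or mast cell lists. With the refitted background 12 of their members were lower and 1 higher over the list alone. With the planned background 2 members (Camp and Ngp) were lower and 0 higher, too few for the criterion set for this count. Markers of a cell type can move together in the same dams, so the count does not decide the question. The list means per dam differed by -0.115, -0.267 and -0.104. Their exact permutation p was 0.159, 0.0873 and 0.246, two-sided and unadjusted, and the same after the refit. A rise in some kinds of cell stays open, and that carbon black raised these genes is a hypothesis.

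The plasma cell and immunoglobulin genes were higher in 13 of 13 members at the high dose (median 0.288), and the mean per dam differed by 0.467 (exact permutation p = 0.0159, two-sided, unadjusted). Of 5 high-dose dams 4 lay above the highest control (0.178), which argues against 1 or 2 dams as the whole source, but dams 62 (0.833) and 65 (0.657) lay well above dams 60 (0.315), 63 (0.44) and 64 (0.0896). The call of the wider B and plasma cell list ended without dam 62 (adjusted p = 0.0609) or 65 (0.218). For that wider list the exact permutation p was 0.222 (adjusted p = 0.61). Of 14 B cell members 9 were higher (median 0.0593). Lymph node or thymus tissue taken along at dissection cannot be told apart from a change in the lung. The thymus and lymph node list changed by 0.168 and the B cell members by 0.206 of the plasma cell change, but the difference from 0.5 of that change had an exact permutation p of 0.0714, two-sided.

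Other splits of the arrays into groups of the same sizes were fitted, 100 for each count with the real one included. For the high dose 1 split, the real one, reached the real 14 genes (highest other 12), and 1 reached the 61 of the refitted background (highest other 34). For the trend 1 split reached the real 15 (highest other 0). These counts argue against chance, though only among splits that ignore the slides, and 100 splits cannot show a share under 1 in 100. For the high dose the splits kept the low-dose and medium-dose arrays in the fit. With only the arrays of that contrast 1 gene passed, not one of the 14. For high against medium dose 3 splits reached the real 6 (highest other 9), which argues against chance among splits that ignore the slides. However, 2 medium-dose arrays were alone on their slide, and the count was 1 with the slide as a fixed block, and 0 with scan date as a block or without those 2 arrays. With the refitted background 4 splits reached the 19 genes of high against medium dose, but the highest other gave 251. What set that split apart was not tested. For the trend 2 reached 56, with 76 as the highest other. The splits say nothing about chance for the gene counts at the medium (100 splits, real 0, highest other 0) and low dose (100 splits, real 0, highest other 3), since any split reaches a count of 0. Chance cannot be excluded for the list counts at the high (57 splits, real 12, highest other 21), medium (79 splits, real 8, highest other 18) and low dose (73 splits, real 9, highest other 24).

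Among the controls, dam 14 stood apart for Npnt 2.983 (others 2.543 to 2.651), Oas2 0.4828 (-0.3959 to -0.1493) and Siglecf 3.07 (2.483 to 2.618), and for the list means of heart and skeletal muscle -1.08 (0.00952 to 0.435), eosinophil and mast cell 0.26 (-0.121 to -0.0281) and macrophage identity genes 0.324 (-0.119 to -0.0464). Control 15 did so for Bub1b -2.759 (-2.475 to -2.442), Cdc20 -2.964 (-2.351 to -2.123) and Gadd45g -0.5833 (-0.3519 to -0.2699), and control 7 for immediate early genes 0.398 (-0.15 to -0.037). At the low dose these were dam 28 for Ddb2 -0.04165 (-0.1053 to -0.08926), dam 31 for Saa3 -1.481 (-2.373 to -2.122) and dam 36 for Egr2 -0.9613 (-0.4918 to -0.325).

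Medium-dose dam 46 stood apart in its spread around the group mean (SD 0.2247, others 0.1284 to 0.1558), for Il1rn 0.1286 (0.4515 to 0.5651) and for heart and skeletal muscle genes 0.52 (-1.05 to -0.751). Medium-dose dam 47 did so for Ngp 1.14 (0.07842 to 0.345), Nppb -0.1459 (-0.3801 to -0.3274), cytokines 0.11 (-0.0791 to -0.0532) and neutrophil markers 0.195 (-0.488 to -0.329), and dam 50 for Npnt 2.639 (2.368 to 2.439). At the high dose these were dam 60 for Pdgfrb 2.208 (1.722 to 1.831), dam 63 for Timp1 -0.9097 (-2.288 to -1.947) and dam 64 for Lor 0.3506 (0.4371 to 0.4722). High-dose dam 65 did so for Lamp3 4.238 (4.505 to 4.609), Npnt 1.966 (2.403 to 2.535) and cartilage, thyroid and squamous genes 0.196 (-0.0219 to 0.0396).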

How the results depend on the processing

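The refitted background, and every alternative for the share of genes with the same direction, were chosen after the data had been seen. Of 40 alternatives for the 14 genes at the high dose, 22 stayed within 1.5 times that count and 18 did not. For named genes 3868 of the values kept their direction and side of the threshold, 129 gained and 77 lost it. Most named genes were not called to begin with, so only those called at the high dose could lose a call. All 77 losses are theirs, from 1 of 38 values for Cxcl5 to 14 of 39 for Clec5a and 20 of 38 for Olfr32. Where values moved, the cause was not tested, except that fewer arrays or genes enter by construction where arrays or dim probes are left out, and that the estimated correlation widens the list test. Probes in place of genes gave no values for lists, named genes or shared direction, and the arrays of each contrast alone gave none for the trend or shared direction.

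At the high dose the count was 184 without background correction, 207 with the deposited value table, 9 with the software's log ratio, 3 with median centring, 4 with probes well above background on all arrays, 50 with the slide as a random block, 29 with array weights, 1 with only the arrays of the contrast, 61 with the refitted background and 110 with that and the slide as a block. At the medium dose it was 5 without background correction and 1 with array weights, the value table or the refitted background, and at the low dose 1 without background correction or with the value table. High against medium dose gave 21 without background correction, 11 with median centring, 22 with Cy5 alone or the value table, 1 with the slide as a fixed and 14 as a random block, 0 with scan date as a block, without the slide 6 arrays or with only the arrays of the contrast, 10 with trend and robust options, 14 with array weights and 19 with the refitted background. The trend gave 232 without background correction, 3 with the log ratio or median centring, 29 without a dim filter, 5 with probes bright on all arrays, 27 with the slide as a random block, 34 with array weights, 271 with the value table, 56 refitted and 76 refitted with the slide as a block. The share with the same sign at the low dose, 50% as reported, was 87.5% without background correction, 78% with the slide as a random block, 89.37% with the value table, 77.05% refitted and 85.45% refitted with the slide as a block.

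The number of lists at the high dose was 19 with Cy5 alone, 0 with an estimated correlation and 1 by fry. At the medium dose it was 16 with median centring, 5 with slide or scan date as a fixed block, 15 refitted and 0 with an estimated correlation or by fry, and at the low dose 0 by those 2. With Cy5 alone, and in no other alternative, 4 named genes turned their direction: Olfr32 -0.044, Myl2 0.021, Comp 0.011 and Aldh3a1 -0.026. Leaving out each array in turn gave 4 to 59 genes at the high dose, 0 to 1 at the medium, 0 to 0 at the low, 0 to 34 for high against medium and 4 to 63 for the trend. It gave 6 to 14, 6 to 13 and 8 to 13 lists at the high, medium and low dose, and 66.67% to 93.33% (medium) and 25% to 79.66% (low) with the same sign. Over all alternatives the adjusted p of the chemokine list at the high dose ranged from 2.6e-21 to 0.167 and that of acute phase proteins from 4.79e-16 to 0.248. The share of probes with Cy5 well above background, 63.3% to 77.8% per array, limits which genes could be tested.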

Other observations

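The genes in both paragraphs were described after their values had been seen, other than Siglech, Prf1, Klrb1c, Ncr1 and Foxp3. Siglech, a receptor of plasmacytoid dendritic cells, lay lower than in every control in all 15 exposed dams, by -0.37 at the low, -0.46 at the medium and -0.31 at the high dose. Its value was lower than the control on 5 of 5 slides at the low and high dose and 3 of 3 at the medium dose. By limma it did not pass with the background model of the plan (adjusted p = 0.656, 0.0993 and 0.13 at the low, medium and high dose). After the refit it passed at the medium and high dose (adjusted p = 0.00222 and 0.023) and not at the low dose (0.348). Over all alternatives the adjusted p ranged from 0.00573 to 1, 7.78e-05 to 1 and 0.0014 to 1, and the 3 differences share the same 5 controls.

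The T and natural killer cell list was not called at the high dose (refitted adjusted p = 0.0569). Of its 28 genes, 0 rose or fell adjusted over the list alone by limma with the planned background. After the refit, 7 fell, 1 rose and 20 did not pass. Those that fell were the perforin Prf1 (-0.61 ± 0.13), the granzymes Gzmb (-0.51 ± 0.14) and Gzma (-0.49 ± 0.15), the receptors Klrb1c (-0.60 ± 0.14), Klrd1 (-0.51 ± 0.12) and Ncr1 (-0.34 ± 0.11), and the T cell coreceptor chain Cd8b1 (-0.41 ± 0.14). Foxp3, the transcription factor of regulatory T cells, rose (0.28 ± 0.08), from a signal that was dim in controls. Genes of the same cell types that did not pass included Nkg7 (-0.20 ± 0.13), Eomes (0.11 ± 0.11), Cd247 (-0.05 ± 0.10) and Cd8a (-0.02 ± 0.07). Over all genes 0 of these 8 passed by limma (lowest adjusted p 0.0531, for Prf1, with 0.0175 to 0.905 over the alternatives).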
